A study of Mus musculus with 10 samples.

How the data were processed

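RNA of regulatory T cells (Tregs) sorted from mouse spleen was profiled in 10 libraries, 5 from mice labelled WT and 5 from mice labelled KO, each library from a separate mouse by its mouse id. The WT animals carried Foxn1Cre with 1 floxed and 1 wild-type allele of NIK, and the KO animals carried Foxn1Cre with both alleles floxed. NIK is the kinase encoded by Map3k14, and Foxn1 is a transcription factor of thymic epithelial cells, so the deletion was directed to the thymic epithelium and not to the Tregs. Deletion in other cells that express Foxn1 was not examined. Per the labels' protocols, cells were sorted into lysis buffer, RNA was isolated with an RNeasy kit and held to a quality number above 9, cDNA was tagmented and amplified with Nextera XT, and libraries were sequenced as single 100 bp reads on a NovaSeq instrument. The surface markers of the sort, the sex and the age of the animals are not given in the sources used here.

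The deposited table held whole-number counts per Ensembl gene for 25700 genes in 10 columns, with no normalization applied. For these counts the submitters' processing notes name STAR, featureCounts, Subread, DESeq2, edgeR and the genome build GRCm38, without the step each was used for. Tool versions, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Counts of genes that overlap another gene are uncertain for that reason, and 44 of the 136 genes named by the rule below had exons that overlap another annotated gene, 30 of them on the opposite strand. Members of families with related sequences, some of them near-identical, are uncertain too where reads map to several members. Such families include the guanylate-binding proteins, Ccl3 and Ccl4, haemoglobins and duplicated Trav segments. Columns carried the mouse ids and were matched to samples through them, and no column was left out. Symbols were found for 25587 identifiers, and 113 kept their identifier. Coordinates are those of the GENCODE M21 annotation of GRCm38.

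Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test on the counts, with TMM scaling, filterByExpr at its minimum count of 10 and minimum total of 15, genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are KO over WT. Levels are TMM-normalised CPM with the SD over 5 libraries, and errors of log2 fold changes are standard errors. Of 38 gene lists, 36 were tested with camera of limma 3.58.1 at its preset correlation of 0.01, again with an estimated correlation, and with fry. The sex-linked list served as a check of the animals, and of 218 immunoglobulin variable segments 0 passed the count filter, so that list was not tested. Usage of Trbv and Trav segments was tested with edgeR on the counts of the locus with the locus total as library size. Shannon entropy of Trbv counts, in nats after thinning each library to 10291 Trbv counts, was compared by a two-sided exact permutation test over the 252 assignments of 5 libraries, whose smallest p is 0.00794.

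The 38 lists, the tests and a rule for the genes to be named were fixed before the data were examined. The rule took Map3k14 and Foxp3, the 12 largest increases and the 12 largest decreases among called genes with a mean of at least 1 log2 CPM, and up to 4 called members with the smallest p from each list. Predicted genes, pseudogenes, receptor segments and sex-linked genes were left out of the largest changes. Other genes named in the text were chosen after their values were seen: Ddx3y, Gzmb, Cd44, Havcr2, Btla, Tox, Ifng, Ccr7, Cd226, Il2, Gpr83, Nrp1, Il2ra, Ikzf2, Il4, Areg, S100a9, Trac, Trbc1, Trbc2, Cd79a, Psmb9, Calr, Tap1, H2-K1, Ccl1 and Cxcl10.

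The mouse ids fall into a series that begins with 26 (WT3 to WT5 and KO3 to KO5) and a series that begins with 27 (WT1, WT2, KO1 and KO2). The id of KO4 has 3 digits and was placed by its first 2. Fits within each series and the interaction of genotype with series were run, since each series holds both genotypes. Each column name also ends in a second number, whose meaning is not given. Within each series every KO library has a lower second number than every WT library. Whatever this number stands for cannot be told apart from genotype there.

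Totals ran from 13913767 counts in KO4 to 28477963 in KO3, so 3 counts, the most that a count of 0 allows at a confidence of about 95%, were worth between 0.105 and 0.216 CPM per library. These floors cover counting error only, because the labels name no molecular identifiers. Where all WT libraries had 0 counts, a fold is given as a lower bound against 3 counts over the 5 WT libraries together, or over those that remain where a library is left out. Replicates were not copies of one another: every pair within a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 17.6.

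The procedures were tested on simulated counts with the real means, dispersions and library sizes, in which 200 genes were changed. In that simulation of KO against WT over 12435 genes, 23.9% of genes changed by 1.5-fold, 46.3% of those changed by 2-fold and 89.4% of those changed by 4-fold were recovered with the right sign, and 3 of 12240 unchanged genes were called. In a simulation with no change over 12736 genes, 0 genes were called. Simulated genes varied independently, and the changed ones were few and balanced between higher and lower. These rates need not hold for the real comparison, in which far more genes were called.

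Alternatives were DESeq2 size factors, upper quartile and library-size scaling, other count filters, DESeq2 1.42.0, limma-voom with and without quality weights, robust dispersion, a replicate block, the mouse id series, a Y-linked term, a surrogate variable from sva 3.50.0, leaving out each library, and other thresholds. Thinning to equal totals, a term for myeloid transcripts, a term for the number of genes detected and a correction for transcript length and GC content were added after the data were seen, as were list, segment and entropy values within each mouse id series, the interaction without each library, tests of gene families after the length and GC correction, and the Th1-type list without members of the CD8 T and NK cell list. Of the tested genes, 99.9% had a length. Across genes, which are not independent replicates, the log2 fold change had a Spearman rho of -0.144 with transcript length and of 0.0126 with GC content.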

Results

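RNA of Tregs from the spleen of C57BL/6 mice was sequenced and counted per gene. Tregs are the CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. The 10 libraries came from 5 WT and 5 KO mice. Library totals, in units of 1e6 counts, were 27.03, 20.9, 23.1, 24.3 and 22.02 for WT1 to WT5 and 27.2, 24.8, 28.5, 13.9 and 26.4 for KO1 to KO5. The group means of 23.5 ± 2.34 and 24.2 ± 5.89 (SD, n = 5 each) differed by less than the spread between libraries (two-sided exact permutation p = 0.865). The number of genes with a count was 14179 ± 536 in WT and 14076 ± 1044 in KO (SD, n = 5, exact permutation p = 0.841). The Y-linked gene Ddx3y stood at 83.0 to 145 CPM of the library total in 9 libraries and at 0.239 CPM in WT2.

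The comparison asks how a deletion of NIK directed to thymic epithelial cells, the stromal cells that instruct T cell development, is reflected in the transcripts of Tregs in the spleen. Cells sorted as Tregs from KO mice had more transcripts of effector, suppressive and type 1 inflammatory genes. Libraries of sorted cells do not show whether such transcripts came from Tregs or from other T cells in the sort. Of 36 gene lists tested, 14 passed camera, 10 of them higher and 4 lower in KO, and 6 of the 14 also passed with an estimated correlation (effector Treg, suppressive, Th1-type, interferon-gamma GTPase, inhibitory receptor and conventional CD4 T cell genes). The lists are not independent, since 50 genes were in more than 1 of the 36. Lists of proliferation and glycolysis passed as higher and that of resting Tregs as lower with the preset correlation, but adjusted p = 0.213 with an estimated correlation for each of the 3. By fry, which tests whether members move one way and does not compare them with other genes, 21 lists passed. They were 13 of the 14, without the ribosomal list (adjusted p = 0.147), and 8 that camera did not pass. Of 12736 genes tested, 2379 were higher and 2068 lower in KO, so 4447 genes or 34.9% changed. Changes of at least 2-fold were found for 897 higher and 912 lower genes, and of at least 4-fold for 215 and 331. For 3456 of the tested genes (27.1%) no WT library overlapped a KO library, where chance gives 0.794%. The first principal component carried 50.4% of the variance and separated the genotypes, and within each genotype also the mouse id series. KO libraries lay at 15.5 to 33.2 in series 26 and at 90.4 and 123 in series 27. WT libraries lay at -69.3 to -62.0 in series 26 and at -46.2 and -46.0 in series 27.

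**Figure D1:**
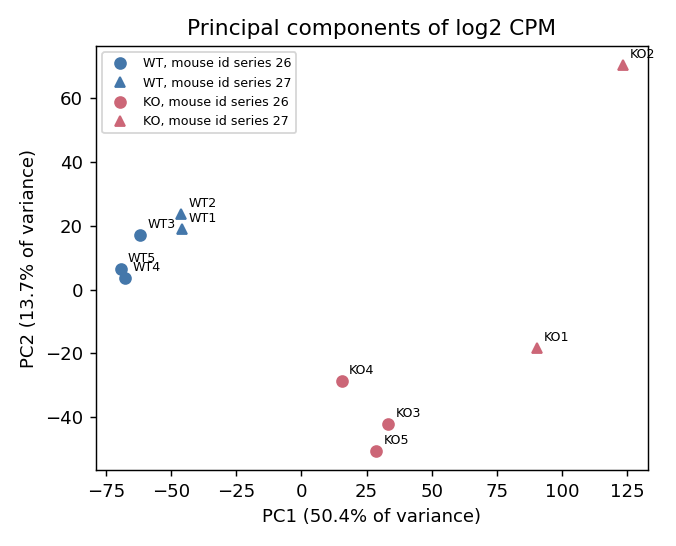
Scores of the 10 libraries on the first and second principal components of log2 CPM, with the percent of variance on each axis, colour for genotype and shape for mouse id series. WT libraries lie between -69.3 and -46.0 on the first component and KO libraries between 15.5 and 123, with KO2 farthest from the others on both axes.

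Calls were found in both mouse id series, with 2242 genes higher and 1976 lower in series 26 (3 mice per group) and 1909 higher and 1677 lower in series 27 (2 mice per group). The 2 series share no library, but in both the second number of the column names follows genotype. Of 12445 genes tested in both, 1349 were higher in both and 1061 lower in both, where unrelated lists of these sizes would share 334 and 252, and 7 were called in opposite directions. The log2 fold changes had the same sign in both series for 78.8% of these genes, where unrelated signs give 50.0%. The split of the calls depended on the scaling: 53.5% were higher with TMM scaling and 34.9% with library size only, which moved the median of all genes by -0.17 on the log2 scale. The TMM factors themselves followed genotype, with 1.04 to 1.08 in WT and 0.927 to 0.974 in KO (two-sided exact permutation p = 0.00794).

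Map3k14, the gene that encodes NIK (ENSMUSG00000020941, GRCm38 chromosome 11, 103219762 to 103267472), had 25.6 ± 7.26 CPM in WT and 12.6 ± 7.61 CPM in KO (SD, n = 5). Its log2 fold change was -1.03 ± 0.49 (SE) and did not pass the test (edgeR, adjusted p = 0.122). It was called lower in series 26 alone (-0.81, adjusted p = 0.00766) and not in series 27 alone (-1.81, adjusted p = 0.147). Over all libraries it was called lower with the series as a term (adjusted p = 0.0202), the replicate block (0.0251), the number of genes detected as a term (0.0273), 1 surrogate variable (0.0399) and limma-voom (0.0406). Since the deletion was directed to thymic epithelium, its level in Tregs does not check the genotype labels. Foxp3, the lineage factor of Tregs (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), had 904 ± 119 CPM in WT and 1034 ± 392 CPM in KO, a log2 fold change of 0.19 ± 0.22 (adjusted p = 0.521). With 1 surrogate variable it was called higher (0.34, adjusted p = 0.0201), as with voom quality weights (0.45, adjusted p = 0.0309). Its log2 fold change was 0.42 in series 26 (adjusted p = 0.0748) and -0.34 in series 27 (adjusted p = 0.0129), and the difference between the series did not pass (adjusted p = 0.169). Reads of Foxp3 may be shared with neighbouring genes that its exons overlap.

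Transcripts of effector Tregs rose: of 21 measured members of the effector Treg list, 17 were higher, 1 was lower and 3 were not called (also 17 and 1 adjusted over the list alone). Il10, an immunosuppressive cytokine (ENSMUSG00000016529, chromosome 1, 131019845 to 131024974), rose from 6.07 ± 1.45 to 92.9 ± 24.7 CPM (log2 3.94 ± 0.23, adjusted p = 7.68e-07). Tigit, an inhibitory receptor (ENSMUSG00000071552, chromosome 16, 43648867 to 43664146), rose from 111 ± 10.2 to 645 ± 46.3 CPM (log2 2.54 ± 0.10, adjusted p = 4.26e-08). Prdm1, which encodes the effector regulator Blimp-1, rose by 2.71 on the log2 scale, and the costimulatory receptor Icos by 2.32. The cytotoxic granule protease Gzmb rose from 41.3 ± 14.7 to 2107 ± 1041 CPM, and the adhesion receptor Cd44 fell by 0.50. In each KO library Il10, Tigit, Prdm1, Icos and Gzmb lay above every WT library. The median log2 fold change of the list was 2.0 (2.08 in series 26 and 2.02 in series 27), and camera gave an adjusted p of 2.78e-30, or 0.00152 with an estimated correlation.

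Of 13 measured suppressive molecules, 9 were higher, 1 lower and 3 not called, with the same counts adjusted over the list alone. Il10 and Gzmb are among the members that this list shares with the effector list. Lag3, Fgl2, Entpd1 and Ctla4, which restrain other T cells through receptor contact, a secreted protein, adenosine production and competition for costimulation, rose by 2.68, 2.59, 2.11 and 1.41 on the log2 scale. The median was 2.11 (1.71 and 1.94 in series 26 and 27), and the list passed camera with an adjusted p of 3.20e-15, or 0.000923 with an estimated correlation. Inhibitory receptors were split: 5 of 12 were higher, 2 lower and 5 not called, again with the same counts adjusted over the list alone. Of the higher ones, Ctla4, Lag3 and Entpd1 are also in the suppressive list and Tigit in the effector list. Their rise is therefore not separate from that of those lists. Havcr2, the receptor TIM-3, rose by 5.95, while Btla and Tox, a receptor and a transcription factor of chronically stimulated T cells, fell by 1.02 and 0.95. The median was 0.39 (0.39 and 0.61 in the 2 series, 0.22 with library size only), with an adjusted p of 3.86e-06, or 0.00752 with an estimated correlation.

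Genes of type 1 (Th1) T cells rose: 11 of 13 measured members were higher, 0 lower and 2 not called, as also adjusted over the list alone. Tbx21, the lineage factor of Th1 cells (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331), rose from 9.79 ± 3.38 to 168 ± 78.6 CPM (log2 4.10 ± 0.39, adjusted p = 2.39e-05), with 3.89 in series 26 and 4.24 in series 27. Its target chemokine receptor Cxcr3, which the effector Treg list also holds, rose by 3.35 and the cytokine Ifng by 4.99. The list had a median of 3.29 (2.65 and 3.03 in the 2 series) and an adjusted p of 5.11e-16, or 0.0442 with an estimated correlation. The CD8 T and NK cell list, which holds 3 of the 13 members (Nkg7 and Ccl5 among them), had a median of 2.07 (adjusted p = 0.232). Without these 3, a choice made after the data were seen, 9 of 10 Th1 members were higher (median 3.72, adjusted p = 7.58e-16, or 0.0321 with an estimated correlation). The list of interferon-gamma response GTPases, which act in defence inside cells, also holds a transcription factor and a signalling inhibitor that are not GTPases. Of its 14 members, 13 were higher and 1 was not called, as also adjusted over the list alone. Iigp1 rose from 20.7 ± 3.30 to 318 ± 64.5 CPM and Gbp3 by 2.44 on the log2 scale; the median of the list was 1.39 (1.34 and 1.44), with an adjusted p of 6.38e-29, or 0.00546 with an estimated correlation. GTPases of this list have near-identical relatives, so their counts are uncertain where reads map to several of them.

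**Figure D2:**
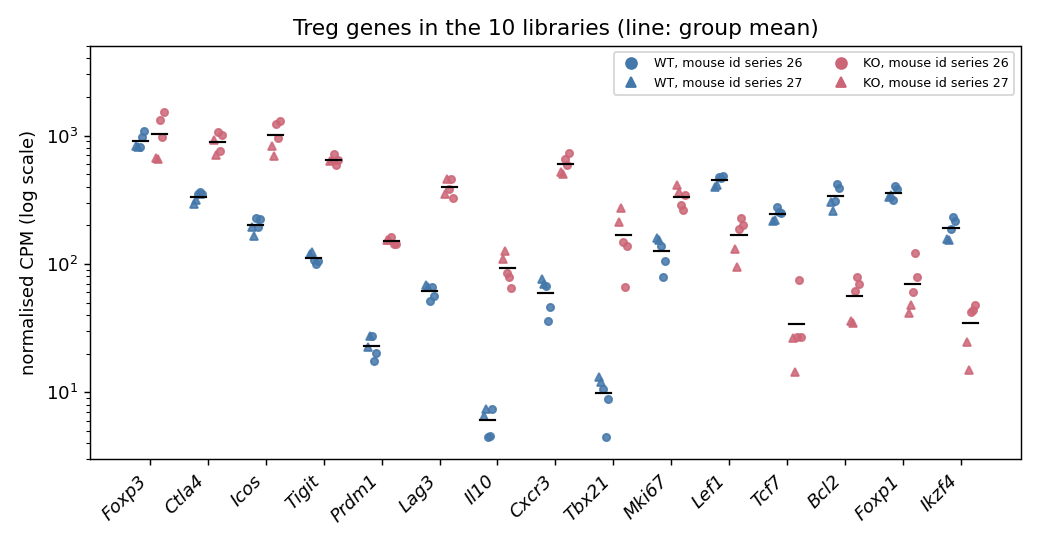
Normalised CPM of 15 genes in each library on a log scale, with a line at the group mean, colour for genotype and shape for mouse id series. Foxp3 overlaps between groups, whereas Il10 lies between 4.49 and 7.41 CPM in WT and far above in KO, and Tcf7 lies lower in every KO library than in any WT library.

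Genes of resting Tregs fell: of 16 measured members, 0 were higher, 12 were lower and 4 were not called (15 lower adjusted over the list alone). Tcf7, a transcription factor of naive and memory T cells (ENSMUSG00000000782, chromosome 11, 52252371 to 52283014), fell from 243 ± 25.9 to 34.0 ± 23.7 CPM (log2 -2.85 ± 0.36, adjusted p = 0.000148). Bcl2, a survival factor (ENSMUSG00000057329, chromosome 1, 106538178 to 106714274), fell from 338 ± 67.0 to 56.4 ± 20.1 CPM, and Foxp1, a factor of T cell quiescence, fell by 2.35 on the log2 scale. Ccr7, a homing receptor for lymph nodes, fell by 2.46. The median was -2.35 (-1.95 in series 26 and -3.22 in series 27), with an adjusted p of 3.22e-12 by camera, and adjusted p = 0.213 with an estimated correlation. The conventional CD4 T cell list, 6 of whose 11 members the resting list also holds, had 1 member higher, 5 lower and 5 not called (1 and 7 adjusted over the list alone). Lef1 and Cd226 fell by 1.42 each, and the cytokine Il2 rose by 2.69. Its median was -1.42 (-1.38 and -1.89), with an adjusted p of 2.26e-05, or 0.0206 with an estimated correlation. The 6 shared members had a median of -2.02 and the other 5 of -0.26.

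Of 17 Treg identity genes, 5 were higher, 6 lower and 6 not called (5 and 7 adjusted over the list alone), and the list did not pass (median -0.21, with -0.14 and -0.49 in the 2 series; adjusted p = 0.546), but passed as lower in series 27 alone (adjusted p = 8.44e-05). Ctla4 was among the higher genes, while Ikzf4, encoding Eos, and the receptor genes Gpr83 and Nrp1 fell by 2.45, 2.81 and 1.46. Il2ra, the high-affinity chain of the interleukin-2 receptor, had a log2 fold change of 0.02 and Ikzf2, encoding Helios, of -0.39 (adjusted p = 0.0504). The identity list passed in series 27 with the preset correlation, the only setting of camera run within a series. At that setting other splits of the 10 libraries passed up to 16 lists while calling 0 genes. Passes in 1 series alone, here and below, are therefore weak evidence of a difference between series. Of 11 genes of immature thymocytes and recent thymic emigrants, 2 were higher, 3 lower and 6 not called, also adjusted over the list alone (median -0.48, with -0.56 and -1.03 in the 2 series; adjusted p = 0.260, and 0.0148 by fry). Sox4 and Dntt fell by 5.28 and 3.92, and Plac8 rose by 3.49. The value of Sox4 was -7.92 without KO1, and its call was lost in series 27 alone (adjusted p = 0.0538), as was that of Dntt in series 26 alone (adjusted p = 0.0767).

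Proliferation genes rose together: all 20 measured cell cycle genes were higher, as also adjusted over the list alone. Mki67, the proliferation marker Ki-67, rose from 127 ± 33.7 to 334 ± 58.8 CPM (log2 1.39 ± 0.19), Rrm2, which supplies deoxynucleotides, by 1.89, and the cyclin gene Ccna2 by 1.80. The median was 1.40 (1.53 and 1.27 in the 2 series), with an adjusted p of 7.06e-17, and adjusted p = 0.213 with an estimated correlation. Of 15 glycolysis genes, 13 were higher, 0 lower and 2 not called (14 higher adjusted over the list alone); Gapdh rose by 1.56, Pgk1 by 1.65 and Pkm by 1.12. The median was 1.12 (0.95 and 1.33), with an adjusted p of 1.96e-08, and adjusted p = 0.213 with an estimated correlation. Oxidative phosphorylation genes in the nucleus were higher for 13 of 20 and not called for 7 (15 higher adjusted over the list alone). Cox7a2 rose by 1.03 and Atp5b by 0.59, and the median was 0.46 (0.48 and 0.38, and 0.29 with library size only), with an adjusted p of 9.31e-05, and adjusted p = 0.553 with an estimated correlation.

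The mitochondrially encoded genes moved the other way: 0 of 8 were higher, 6 lower and 2 not called (7 lower adjusted over the list alone). mt-Nd4, a subunit of complex I, fell from 603 ± 66.8 to 349 ± 29.4 CPM, and mt-Cytb, of complex III, fell by 0.59 on the log2 scale. Their median was -0.56 (-0.50 and -0.58), with an adjusted p of 0.000947, and adjusted p = 0.219 with an estimated correlation. Of 81 cytosolic ribosomal protein genes, 20 were higher, 4 lower and 57 not called (17 and 4 adjusted over the list alone). Rpsa rose by 0.93 and Rps13 by 0.64, while Rps27 fell by 0.70. The median was 0.20 (0.14 and 0.27) and 0.03 with library size only, with an adjusted p of 0.0310, and adjusted p = 0.773 with an estimated correlation. The call was lost without WT1, WT2, KO2, KO3 or KO5. It was also lost by camera with the series as a term (adjusted p = 0.0623), with library size only (0.274) and in series 26 alone (0.484).

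**Figure D3:**
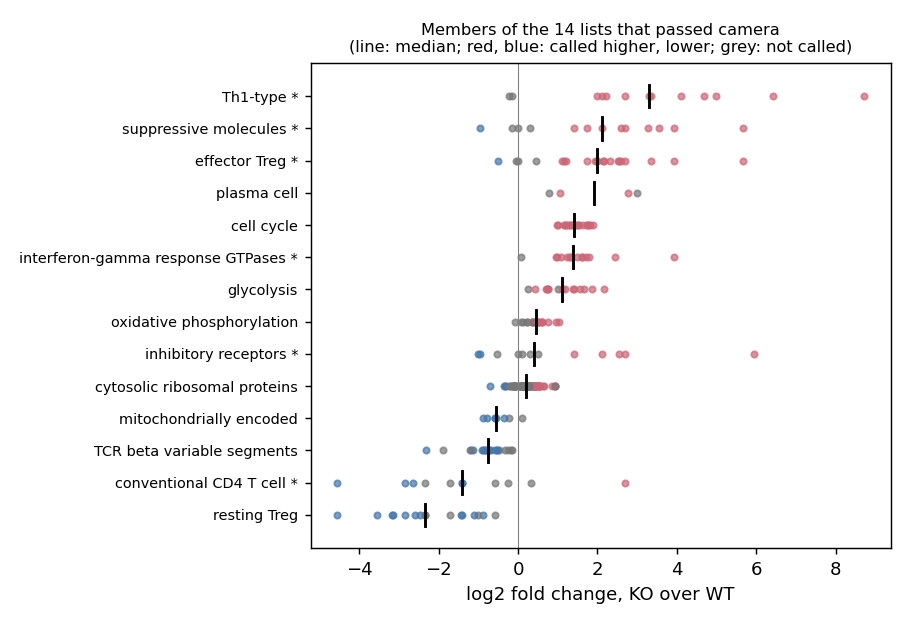
Log2 fold changes (KO over WT) of the members of the 14 lists that passed camera, as points coloured by the call of each gene, with a line at the list median; asterisks mark the 6 lists that also passed with an estimated correlation. Medians run from -2.35 for resting Treg genes to 3.29 for Th1-type genes.

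Several lists did not pass camera although single members changed. Type I interferon response genes were 8 higher, 3 lower and 6 not called of 17 (8 and 5 adjusted over the list alone), with a median of 0.24 (0.20 and 0.30 in the 2 series) and an adjusted p of 0.211, or 0.0223 by fry; in series 27 alone the list passed camera (adjusted p = 0.0411). Oas1a rose by 1.98. T cell receptor activation genes were 3 higher, 6 lower and 8 not called (4 and 9 adjusted over the list alone), with a median of -0.39 (-0.28 and -0.65 in the 2 series, adjusted p = 0.0534); with library size only, or without WT3, WT4, WT5 or KO2, the list passed (adjusted p from 0.0223 to 0.0416), as by fry (0.00184). Rel, an NF-kB subunit, fell by 1.30, and Cd200 by 1.72. Immediate-early genes had 1 higher, 4 lower and 10 not called, also adjusted over the list alone (median -0.22, with -0.18 and -0.24 in the 2 series, adjusted p = 0.173, and 0.000496 by fry); Btg2 fell by 1.81 and Jun by 1.01.

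Alternative NF-kB genes, the pathway in which NIK acts, were 2 higher, 1 lower and 9 not called, as also adjusted over the list alone (median 0.000827, with -0.01 in series 26 and -0.22 in series 27, adjusted p = 0.546). Tnfrsf1b, a receptor for tumour necrosis factor, rose by 1.43 and Birc3 fell by 0.62. Canonical NF-kB genes were 3 higher, 4 lower and 8 not called (4 and 4 adjusted over the list alone), with a median of -0.02 (-0.0033 in series 26 and -0.06 in series 27, adjusted p = 0.503). IL-2 and STAT5 genes were 7 higher, 4 lower and 6 not called (8 and 4 adjusted over the list alone; median 0.24, with 0.43 and 0.01 in the 2 series, adjusted p = 0.546). Apoptosis genes were 7 higher, 3 lower and 6 not called, also adjusted over the list alone (median 0.25, with 0.21 and 0.24 in the 2 series, adjusted p = 0.638, and 0.00725 by fry). Fas, a death receptor, fell by 1.54. Migration and adhesion genes were 6 higher, 7 lower and 13 not called (8 and 7 adjusted over the list alone). Their median was 0.14 and -0.03 with library size only, and 0.16 in series 26 and -0.50 in series 27 (adjusted p = 0.270). Cholesterol synthesis genes were 6 higher, 1 lower and 10 not called, also adjusted over the list alone (median 0.40, with 0.57 and 0.17 in the 2 series, adjusted p = 0.0991, and 0.0162 by fry), and passed in series 26 alone (adjusted p = 0.00508).

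The Th2-type list had 4 members higher, 2 lower and 4 not called, also adjusted over the list alone (median 0.47, with 0.62 and 0.20 in the 2 series, adjusted p = 0.326, and 0.0148 by fry). Il4 and Areg rose by 3.45 and 3.56, while the lineage factor Gata3 fell by 0.87. Of 7 Th17-type genes, 1 was higher, 1 lower and 5 were not called, also adjusted over the list alone (median -0.51, with 0.10 in series 26 and -0.90 in series 27, adjusted p = 0.670), with Cxcr6 higher by 3.59 and Ccr6 lower (log2 -2.62). Tfh and Tfr genes were 3 higher, 2 lower and 7 not called (5 and 2 adjusted over the list alone; median 0.32, also with Sostdc1 at its lower bound, with 0.26 in series 26 and -0.18 in series 27; adjusted p = 0.435). Bcl6, the lineage factor of follicular T cells, fell by 2.90.

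The largest changes included genes with 0 counts in all 5 WT libraries. Against 3 counts over the WT group (0.0241 CPM), Gcg, the glucagon gene (ENSMUSG00000000394, chromosome 2, 62474530 to 62483650), was at least 1060-fold higher. Its bound leaned on KO1, with 83.9 CPM against 1.18 to 18.8 in the other KO libraries, and was 367-fold without it. Spp1, encoding osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), was at least 675-fold higher and Sostdc1 at least 141-fold (502 and 109 without KO1). Gzmk, a granule protease with 2 counts in WT, both in WT2, had a ratio of 603 (95% counting interval 167 to 4985) and was at least 331-fold higher without WT2. Enpp2, Il21 and Adgrg5 had WT counts in WT4 alone. They rose by 7.69, 6.27 and 6.23 on the log2 scale, by at least 8.02, 8.27 and 7.09 without WT4, and by 5.55, 4.28 and 4.12 in series 26 alone. The chemokines Ccl3 and Ccl4 rose by 8.19 and 8.0, Serpina3f by 7.11, Gzma by 6.65 and Il12rb2 by 6.41. Without 1 library Gzma ranged from 5.56 (without KO2) to 8.86 (without WT1). With limma-voom the calls of Gcg, Ccl3, Ccl4, Gzma and Il12rb2 were lost (adjusted p = 0.0572, 0.269, 0.220, 0.210 and 0.0557), as was that of Ccl4 with voom quality weights (0.0547). S100a8 had 140 CPM in KO3 against 0.295 to 7.29 in the other KO libraries. Its log2 fold change was 8.12, and 5.0 without KO3 and 10.3 without WT2, and the call was lost with limma-voom, with voom quality weights and in series 27 alone (adjusted p = 0.159, 0.426 and 0.0749). Cavin1, a component of caveolae (ENSMUSG00000004044, chromosome 11, 100956733 to 100970887), fell from 10.7 ± 3.61 to 0.126 ± 0.177 CPM (log2 -6.52 ± 0.85, adjusted p = 0.000188). St8sia6, a sialyltransferase, fell by 6.16 (74.2 ± 22.7 to 1.24 ± 2.14 CPM), Hdac9 by 5.80, Tmem121b by 5.76, Tdrp by 5.44, Pstpip2 by 5.38, Tspan9 by 5.21, Ampd1 by 5.12, Zfp516 by 5.07, Arhgap20 by 5.06 and Ptger3 by 4.89. Without 1 library these 11 genes stayed called, with values from -7.94 (St8sia6 without KO4) to -4.56 (Ptger3 without KO1). Over all alternatives, the fits within a series among them, they stayed called with a wider range, from -13.3 for St8sia6 to -3.73 for Ptger3. Fitted values that low are no bounds.

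Transcripts of genes listed for other cells were present, at levels up to those of Ighm of the B cell list, which had 894 to 3058 CPM of the library total. Values given further below argue against B cells and plasma cells as the source of Ighm reads. The level of Ighm therefore does not measure how many such cells the sort held. In WT3, WT4 and WT5, Csf1r, a macrophage receptor, stood at 66.5, 61.9 and 32.3 CPM of the library total, and C1qa at 28.8, 24.0 and 13.2 CPM. The myeloid list was 2 higher, 2 lower and 9 not called, also adjusted over the list alone (median -1.53, adjusted p = 0.546), with -1.89 in series 26 and -0.0591 in series 27. Csf1r fell by 1.53 and C1qa by 3.58 on the log2 scale; the first call was lost without WT3 or WT4 and the second without any 1 of 7 libraries, and C1qa was at -5.17 without KO3. Over all alternatives the call of Csf1r was lost in 7 of 31 and that of C1qa in 12 of 29. S100a8 and S100a9 of granulocytes stood at 131 and 78.1 CPM of the library total in KO3. The erythroid and platelet list had 1 higher gene and 6 not called (0 adjusted over the list alone; median 2.10, with 3.03 in series 26 and -1.12 in series 27, adjusted p = 0.546); Hbb-bs, the called gene, had a log2 fold change of 2.59 (adjusted p = 0.0432), and 0.94 without KO3. Its call was lost in 17 of 31 alternatives, among them limma-voom (adjusted p = 0.259), the series as a term (0.102) and the replicate block (1.36, adjusted p = 0.179), and without any 1 of 7 libraries. Plasma cell genes were 2 higher, 0 lower and 2 not called, also adjusted over the list alone. Igkc rose by 2.76 and Txndc5 by 1.07, with a list median of 1.91 (2.08 and 2.29 in the 2 series), an adjusted p of 0.0256, and adjusted p = 0.152 with an estimated correlation; with the series as a term the adjusted p was 0.0687, and in series 27 alone 0.257.

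Of 10 CD8 T and NK cell genes, 4 were higher, 1 lower and 5 not called, also adjusted over the list alone (median 2.07, with 0.87 and 2.44 in the 2 series, adjusted p = 0.232). The list passed as higher in series 27 alone (adjusted p = 0.000389) and with the replicate block (1.94, adjusted p = 0.0402). Nkg7 and Ccl5, which the Th1-type list also holds, rose by 3.29 and 2.69 and Klrb1c, an NK cell receptor, fell by 3.95 (not called in series 27 alone, adjusted p = 0.176). B cell genes were 1 higher, 1 lower and 6 not called, also adjusted over the list alone (median -0.44, with -0.11 and -1.51 in the 2 series, adjusted p = 0.467). Ighm had 1074 ± 94.3 CPM in WT and 1921 ± 909 CPM in KO (log2 0.84, adjusted p = 0.0301), with 1.24 in series 26 and -0.10 in series 27, and the call was lost when any 1 of WT1, WT4, WT5, KO3, KO4 or KO5 was left out, and in 13 of 31 alternatives in all. MHC class II genes were 3 higher, 2 lower and 5 not called (5 and 2 adjusted over the list alone; median 1.0, with 1.19 and 0.56 in the 2 series, adjusted p = 0.503), with H2-Ab1 higher by 3.92 and H2-Ob lower (log2 -2.24). The call of H2-Ab1 was lost with limma-voom (adjusted p = 0.0815), voom quality weights (0.120) and in series 27 alone (0.0518). Dendritic cell genes were 2 higher and 2 not called (2 and 1 adjusted over the list alone; median 0.30, with -0.35 in series 26 and 0.48 in series 27, adjusted p = 0.546). Stromal and endothelial genes were 1 higher, 1 lower and 3 not called (1 and 2 adjusted over the list alone; median -1.41, with -0.99 and -1.84 in the 2 series, adjusted p = 0.467).

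Fewer transcripts of the T cell receptor beta locus and more of the alpha locus were counted in KO. The sum of Trbv segments fell from 950 ± 5.70 to 608 ± 107 CPM and that of Trav segments rose from 207 ± 9.91 to 291 ± 13.98 CPM (SD, n = 5). The constant gene Trac rose from 875 ± 61.6 to 1272 ± 139 CPM, and Trbc1 and Trbc2 fell from 622 ± 36.5 to 411 ± 82.8 and from 1200 ± 142 to 941 ± 101 CPM. By the two-sided exact permutation test p was 0.00794 for each of these except Trbc2 (exact p = 0.0159), or 0.0102 and 0.0179 after adjustment. As a list, Trbv segments were 0 higher, 13 lower and 8 not called of 21 (15 lower adjusted over the list alone). Their median was -0.75 (-0.58 and -1.02 in the 2 series), with an adjusted p of 3.87e-06, and adjusted p = 0.218 with an estimated correlation. Of 64 Trav segments 6 were higher, and 0 adjusted over the list alone (median 0.50, with 0.50 and 0.34 in the 2 series, adjusted p = 0.173). The Trav list passed with library size only (median 0.34, adjusted p = 0.0337) and by fry (0.0040).

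The share of single segments within the beta locus differed as well. Of 21 Trbv segments tested, 4 changed in share, and 7 had an unadjusted p under 0.05. Trbv12-1 (ENSMUSG00000095574, chromosome 6, 41113550 to 41114067) fell from 2.94 ± 0.389% to 0.876 ± 0.338% of Trbv counts (log2 -1.75 ± 0.27, edgeR adjusted p = 3.19e-05), with -1.63 in series 26 and -2.02 in series 27. Trbv13-1 fell from 3.63% to 2.43% (log2 -0.62 and -0.53 in the 2 series; call lost without WT1 or WT4), Trbv3 rose from 9.91% to 13.4% (0.51 and 0.32) and Trbv1 from 6.41% to 9.14% (0.40 and 0.68). Within series 26 alone Trbv12-1 and Trbv3 passed, and within series 27 alone 0 segments did. Entropy of Trbv use fell from 2.84 ± 0.0132 to 2.74 ± 0.0313 nats (SD, n = 5), a difference of -0.101 (exact permutation p = 0.00794). Of 62 Trav segments tested for their share, 0 passed with edgeR, and 2 had an unadjusted p under 0.05. Trav entropy was 3.79 ± 0.0470 in WT and 3.72 ± 0.102 in KO (exact permutation p = 0.183).

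**Figure D4:**
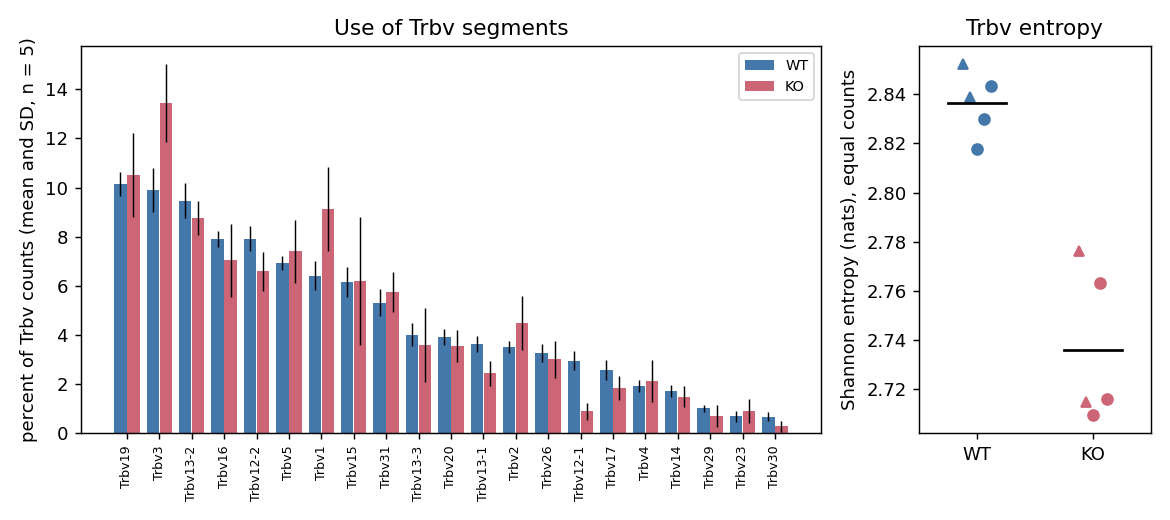
Left, percent of Trbv counts for each of 21 segments as bars for WT and KO with the SD of 5 libraries; right, Shannon entropy of Trbv use per library in nats at equal counts, with a line at the group mean and shape for mouse id series. Trbv12-1 falls from 2.94% to 0.876%, and all KO libraries lie at or under 2.78 nats, below all WT libraries.

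The effect of genotype differed between the mouse id series for 162 genes, 27 with a higher and 135 with a lower log2 fold change in series 27 (edgeR interaction test), and 1926 had an unadjusted p under 0.05. Of the 162, 87 were also called over all libraries, and in 82 of these the difference had the sign of the overall change. Cxcr6 and the glycolytic gene Pfkp rose more in series 27, by 1.97 and 0.67 on the log2 scale, and Ighm and H2-Ob had differences of -1.30 and -1.82. The count was 30, 19, 64, 32 and 56 without WT1 to WT5 and 691, 64, 107, 121 and 57 without KO1 to KO5.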

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

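The explanations weighed here were tested after the patterns had been seen, whereas the counts over other splits of the libraries were planned. Of 288 groups of 5 values examined for a library far from the rest, 14 had one, where chance gives 14.4 at 1 in 20. Levels in these sentences are normalised CPM except where named. Among WT libraries, Gzmk was seen in WT2 alone (0.0907 CPM), and Enpp2 (0.153), Il21 (0.536) and Adgrg5 (0.230) in WT4 alone. Gbp3 was 53.9 in WT1 against 83.3 to 98.6 in the others, Mvd 58.8 against 43.5 to 46.4 in the same library, mt-Nd4 486 in WT3 against 611 to 648, and Klrb1c 1.09 in WT2 against 2.90 to 3.99. In KO, Il12rb2 was 4.36 in KO4 against 38.2 to 62.8, Rpl10 582 in KO4 against 779 to 875, and Cd200 19.2 in KO2 against 52.2 to 70.3. KO4 also had the lowest total of its group, 13.9 against 24.8 to 28.5 in units of 1e6 counts, and the highest TMM factor, 0.974 against 0.927 to 0.940. Ddx3y stood at 0.239 CPM of the library total in WT2 against 117 to 145 in the other WT libraries.

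The effect of genotype differed between the mouse id series, by the interaction test, for 7 named genes. Differences of log2 fold change, series 27 minus series 26, were 1.97 for Cxcr6, 0.67 for Pfkp, -1.30 for Ighm and -1.82 for H2-Ob. Fitted differences of -7.21 for Ptger3, -7.63 for Arhgap20 and -8.54 for Ampd1 rest on KO libraries of series 27 with 0 counts and are no bounds. By camera with the preset correlation, 13 lists differed too, and none did with an estimated correlation. Median differences were -0.47 for Treg identity, -0.89 for resting Treg, 0.46 for Th1-type, 0.13 for type I interferon response and -0.68 for migration and adhesion. Further medians were 0.50 for glycolysis, -0.37 for cholesterol synthesis, -1.35 for B cell, 1.58 for myeloid and -0.64 for conventional CD4 T cell genes. For erythroid and platelet genes the median was -3.70, for Trbv segments -0.53 and for ribosomal proteins 0.16.

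Other divisions of the 10 libraries into 5 and 5, of which 100 of 126 were drawn with the real one among them, tested chance. For the 4447 called genes, 1 of the 100 splits, the real one, gave as many, and the highest of the others gave 0 genes. Chance is thus unlikely, but 1 in 100 is the smallest share that these splits can give. Every other split also mixes the genotypes, which widens the spread within its groups. For the 14 gene lists passing with the preset correlation, 15 of 100 splits gave as many, and the highest of the others gave 16, so chance cannot be excluded for that number. Of the 14 other splits, 10 exchanged 1 WT and 1 KO library. For the 6 lists passing with an estimated correlation, 1 of 100 splits gave as many and the highest other gave 1 list, which makes chance unlikely within the same limit. For the 4 Trbv segments, 1 of 100 splits gave as many and the highest other gave 2, which makes chance unlikely within the same limit. For the 0 Trav segments all 100 splits gave as many, and the highest other gave 1.

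Resting Treg transcripts were lower in KO. A trend of fold changes on transcript length and GC content would need the median of the list to rise above -1 after correction, but it stayed at -2.21. Fewer conventional CD4 T cells in the KO sorts could lower the same genes, and the 5 conventional genes that the resting list does not hold had a median log2 fold change of -0.26, with values from -2.64 to 2.69 (SD 2.0). Members that go both ways leave that explanation open. Genotype remains a hypothesis.

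Entropy of Trbv use was lower in KO. Sampling of few cells may lower entropy in single libraries, but the entropy of the mean shares over 5 libraries differed by -0.0812 (KO minus WT, jackknife SE 0.0136), which argues against it. Genotype stays open as a hypothesis.

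Ighm was abundant although B cell transcripts were nearly missing. B cells in the sort would bring Cd79a, and the lowest ratio of Ighm to Cd79a counts was 251. Plasma cells would bring light chains, and the lowest ratio of Ighm to Igkc counts was 42.2 and the highest 537. Both values argue against these cells as the source. What else brings the reads stays open, and no biological explanation was tested, since the pattern held in both genotypes.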

How the results depend on the processing

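Corrections for length and GC content, thinning, terms for myeloid transcripts and for genes detected, list, segment and entropy values within a series, and the interaction without each library were chosen after the data had been seen. All alternatives kept the sign of every called gene that was called again, and between 3428 genes (without WT4) and 4442 (DESeq2) of the 4447 were called again, except against a 1.5-fold change (1296) and in series 27 alone (2761). Counts were 705 higher and 591 lower against a 1.5-fold change, a stricter threshold by construction. Leaving out 1 library gave 1910 to 2401 higher genes, 1559 to 2125 lower, 13 to 15 lists, 3 to 6 Trbv segments, 0 Trav segments and an entropy difference of -0.111 to -0.0942. With an estimated correlation 6 lists passed, and by fry 21. The direction of the list test turned for Th17-type (0.10 in series 26), apoptosis (0.21 in series 26, 0.24 in series 27), MHC class II (0.56 in series 27), B cell (-0.11 in series 26), myeloid (-0.0591 in series 27), erythroid (-1.12 in series 27) and ribosomal genes (0.10 after length and GC correction); of these lists the ribosomal one alone had passed over all libraries, and the cause was not tested. Whole-library scaling called 15 Trbv and 2 Trav segments and gave Trbv1 -0.15 and Trbv3 -0.19, since it does not remove the lower locus total. Within series 26 and 27, 2 and 0 Trbv segments were called and entropy differed by -0.101 (exact p = 0.1) and -0.100 (exact p = 0.333), the smallest p these designs allow. In series 27 Hbb-bs was -0.20, Ighm -0.10 and Foxp3 -0.34; the cause was not tested. The interaction called 610 genes with DESeq2, 25 with a myeloid term, 8 with a term for genes detected and 19 to 691 without 1 library, where 121 without KO4 was the one count within 1.5 times of 162; the cause was not tested. With the replicate number as a block, 2700 genes were higher and 2368 lower and 15 lists passed. To check for pairing, deviations of each library from its group mean were correlated between WT and KO libraries. Same-numbered libraries had values of 0.0467 to 0.180, and 3 WT libraries correlated best with their own number. Pairs of the same series had a median of 0.124 and other pairs of -0.132. Equal numbers always share a series, so the check cannot tell pairing from series. Subtracting group means pushes some pairs below 0, and the log2 CPM themselves correlated at 0.823 to 0.933 between WT and KO libraries. With the series as a term, 2894 genes were higher and 2655 lower, and 12 lists passed. Depth limits the genes near the floor, from 0.105 to 0.216 CPM.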

Other observations

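Gene families named here were chosen after their values had been seen, so their tests describe these libraries only. Genes of MHC class I presentation rose: 15 of 17 were higher and 0 lower, with a median log2 fold change of 0.67 (0.75 in series 26 and 0.76 in series 27, 0.50 with library size only). Psmb9, a subunit of the immunoproteasome, rose by 1.34, Calr, a chaperone of peptide loading, by 1.31, and Tap1, a peptide transporter, by 1.12, while H2-K1 had a log2 fold change of 0.07. Camera gave an adjusted p of 5.82e-13 over 9 families, or 0.00484 with an estimated correlation, and 0.0548 with an estimated correlation after the length and GC correction. Constitutive proteasome genes were higher for 25 of 34 (median 0.54, adjusted p = 0.333 with an estimated correlation) and genes of tubulins, actins and actin-binding proteins for 16 of 19, with 1 lower (median 0.45 and 0.28 with library size only, adjusted p = 0.124 with an estimated correlation).

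Granule serine proteases were higher for 4 of 6 (median 3.41, with 4.12 and 6.04 in the 2 series, adjusted p = 0.0605 with an estimated correlation) and chemokine ligands for 5 of 9 (median 1.81, adjusted p = 0.311 with an estimated correlation). Ccl1 rose by 3.31 and Cxcl10 by 1.81. Of 297 Zfp zinc finger genes, 7 were higher and 64 lower (median -0.37, adjusted p = 0.311 with an estimated correlation), and of 24 genes of proteins with a SET domain (Kmt2, Kmt5, Setd, Nsd, Ezh and Ash1l genes), many of them histone methyltransferases, 4 were higher and 12 lower (median -0.47 and adjusted p = 0.373 with an estimated correlation, and median -0.19 and adjusted p = 0.618 with the preset correlation after the length and GC correction). Cytosolic chaperonin genes (2 of 7 higher) and GIMAP genes (2 higher and 1 lower of 8) did not pass camera. The ratio of Trav to Trbv counts was 0.218 ± 0.00925 in WT and 0.488 ± 0.0730 in KO (SD, n = 5, exact permutation p = 0.00794), with 0.229 the highest in WT and 0.376 the lowest in KO.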
